A study of Homo sapiens with 51 samples.

How the data were processed

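Lesional skin of 2 people (sources) with pityriasis rubra pilaris was profiled before and at week 8 of anakinra with the GeoMx Human Whole Transcriptome Atlas. In this assay probes linked to DNA barcodes bind RNA in the section, ultraviolet light releases the barcodes of 1 outlined region at a time, and the barcodes are sequenced. The deposited data hold 50 skin regions and 1 technical control without tissue. The series text says that region types were pooled because counts were low, and gives source 1 as 13 regions before and 11 during treatment, whereas the sample labels and the headings of the count table both give 11 and 13.

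Per the file headers, the authors processed reads with the GeoMx NGS Pipeline 2.3.4 (trimmed, stitched, aligned to probe barcodes and collapsed by molecular tag), and the processing notes name build GRCh38. The deposited per-region files hold raw whole counts per probe, not normalised. The deposited count table of the series holds the same counts with zeros raised to 1, which applied to 12.4% of its gene values, so the unit of its values is expected counts (a floor of 1), which the authors deposited without normalisation. The deposited file of the technical control holds counts for 5 probes, whose unit was recorded as other because so few lines could not be checked. The table's headings give the opposite treatment from the sample labels for all 26 regions of source 2, and another region type for 1 of them. The per-region counts and the sample labels were used throughout, and the headings were used as an alternative.

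Aligned reads per region ran from 537,998 to 60,410,565 and gene counts from 11,953 to 1,160,628. Duplicate libraries were looked for as pairs of replicates differing by no more than counting error: over 70 pairs chi-square per degree of freedom was 1.011 to 5.385. Counting error and tissue both limit the precision. Regions before and during treatment could not be paired, because they carry no shared replicate numbers, but the models hold the source, so treatment was compared within each person. The table's headings give a CD3+ and a CD68+ region the same outline number in 17 outlines. Deviations from group means correlated by 0.204 on average within an outline (over 0.1 in 11 of 17) and by -0.061 between outlines of a set.

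Of 18,815 probes 139 were negative probes and 18,676 matched 1 gene each. XIST, Y-linked genes and genes whose level follows a common inherited deletion or haplotype (41 genes present) were removed, which left 18,635, and a gene closely related to one of them was left unnamed in the text. Genes with a count of at least 5 in at least 5 regions were tested (18,626). Effects of treatment came from edgeR 4.0.16 (R 4.3.3) with quasi-likelihood fits, TMM normalisation and Benjamini-Hochberg adjusted p under 0.05. A first model held source by region type (7 levels) and a treatment effect within each source (9 coefficients, common biological coefficient of variation 18.9%), and a second held all 14 combinations of source, region type and treatment. Normalisation factors ran from 0.576 to 2.13. The mean of both sources weights them equally. Regions of 1 biopsy are technical replicates of a person, and n = 2 people, so a further test summed counts into 4 sums of source and treatment. Values per region (CPM) are gene counts scaled to a common total, with no floor added.

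Gene lists (23, with 533 genes, 516 of them tested) were fixed before the data were examined, as were the comparisons and the rule for named genes. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, and adjusted over the lists. The rule named, for the mean of both sources and for each region type comparison, the 10 genes with the smallest p in each direction among those past the threshold with the same sign in both sources, up to 4 members per list, and IL1A, IL1B, IL1RN, IL1R1, KRT5, KRT14, CD3E and CD68. For 1 source and for differences it named the 5 smallest p in each direction. Gene positions came from the reference annotation. On simulated counts of the same depth, edgeR recovered 88% of genes changed 2-fold in the mean and 100% of those changed 4-fold, 31% and 83% in source 1 and 75% and 99% in source 2, and it called nothing when no gene changed. With changed genes present it also called 7, 4 and 7 unchanged genes (mean, source 1, source 2). In the mean DESeq2 called 5 unchanged genes there and limma voom with a random block 88. The simulated regions were independent, with no shift of section or background, so false calls from such shifts were not tested.

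Alternatives chosen beforehand were upper quartile scaling, DESeq2 1.42.0, no filter and a strict filter on low counts, limma voom with source and treatment set as a random block, region type left out, the log2 ratio of gene to negative probe counts as a covariate, and regions left out (those under 50% of the median depth, the Immune regions, and each in turn). Alternatives added after the values were seen were source 2 turned to the table's headings, the count table with its headings, genes above 2 times the negative probes, source 1 without either set of its during regions, and the outline as a block for CD68+ against CD3+ regions. The sets of source 1 were split by the first principal component of strictly filtered genes, with region types centred. Treatment labels were permuted within source and region type 100 times, and region labels 60 times (40 within outlines).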

Results

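Whole-transcriptome in situ counts were obtained from active lesional skin of 2 people (source 1 and source 2) with pityriasis rubra pilaris, a scaling inflammatory skin disease. Skin was taken before and at week 8 of anakinra, a recombinant form of the interleukin-1 receptor antagonist. Regions of tissue were outlined by staining: epidermis (Pan-CK, a keratin stain), CD3+ (T cells), CD68+ (macrophages) and, in source 2, a type named Immune. By the sample labels source 1 had 11 regions before and 13 during treatment, and source 2 had 13 and 13. Epidermis regions numbered 3 in each of the 4 sets, CD3+ and CD68+ regions 4 in each set except source 1 during, with 5 each, and Immune regions 2 per set of source 2.

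Depth was low. Gene counts per region ran from 11,953 to 1,160,628 with a median of 69,798, and the median was 342,240 in epidermis, 65,795 in CD3+, 46,537 in CD68+ and 201,950 in Immune regions. The median gene had 38.4 CPM (counts scaled to a common total per region), against a mean of 32.7 CPM for 139 negative probes that match no transcript, and 16.5% of the genes tested exceeded 2 times that level. The ratio of the mean gene to the mean negative probe averaged 1.21 in source 1 before, 1.60 in source 1 during, 2.01 in source 2 before and 2.32 in source 2 during. Values of most genes therefore lay near those of the negative probes.

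**Figure D1:**
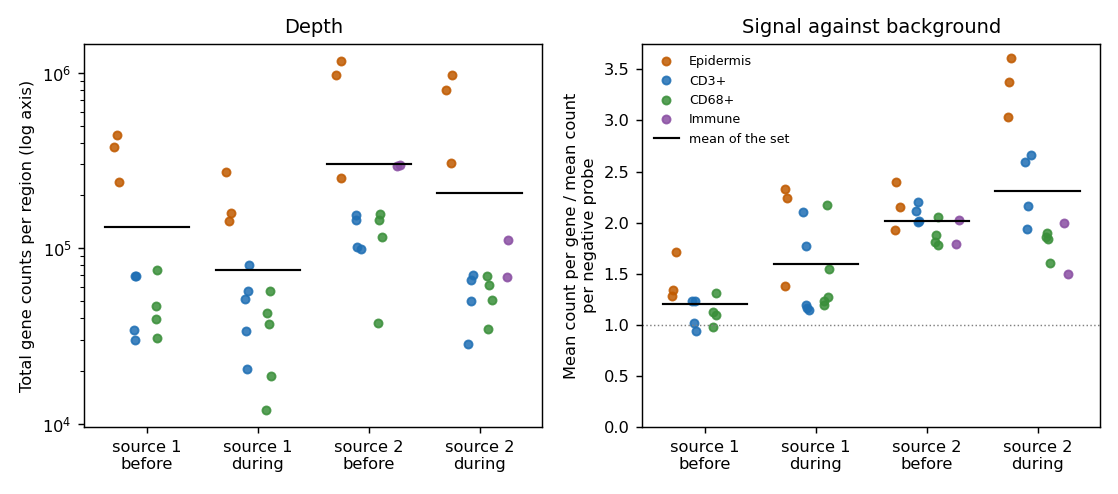
Total gene counts per region on a log axis (left) and mean count per gene divided by mean count per negative probe (right), by source and treatment as labelled; each point is 1 region and the bar is the mean. The mean ratio was 1.21 in source 1 before and 2.32 in source 2 during, and the dotted line marks a ratio of 1.

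Records of treatment conflicted. The deposited count table gives the opposite treatment from the sample labels for all 26 regions of source 2 and the same treatment for all 24 of source 1. For source 1 the series text gives 13 regions before and 11 during, the reverse of the labels and headings. A reversal in source 1 is thus not excluded, and it would turn every direction given for source 1. All values below follow the sample labels, and every direction given for source 2 turns under the table's headings.

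The effect within source 1 asks what differed between its biopsies before and at week 8. Keratins induced in stressed and hyperproliferative epidermis fell: KRT6A (log2 fold change -2.61 ± 0.40, standard error, adjusted p = 6.28e-08), KRT16 (-1.79 ± 0.30, adjusted p = 1.17e-06) and KRT17 (-1.78 ± 0.36, adjusted p = 1.9e-04). Their probes were not tested for binding to one another's transcripts, and KRT6B and KRT6C have no row of their own. KRT17 lost its call without source 1 before replicate 51 (-0.92, adjusted p = 0.192). In epidermis KRT6A went from 1700 ± 1590 CPM (SD, n = 3) to 126 ± 66.1 CPM (n = 3), with every during region below every before region. KRT16 went there from 725 ± 574 to 191 ± 94.8 CPM (n = 3 each), with overlapping ranges. PITX1, a homeobox transcription factor, fell in all 3 region types together (-2.28 ± 0.22, adjusted p = 1.07e-17). So did ANK1 (-2.20), which anchors the membrane skeleton, ATF3 (-2.10), a stress-induced transcription factor, PTN (-2.34), a secreted growth factor, and KDM7A (-1.97), a histone demethylase. ULBP1, a ligand of the natural killer cell receptor NKG2D, rose (3.11 ± 0.27, adjusted p = 2.25e-22). XRCC2 (2.29), a recombination repair gene, rose too, with FAM13B (2.55), GFM2 (2.36) and ZNF714 (2.44).

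By gene list, 19 of 51 measured members of the cornified envelope list fell in source 1 (27 adjusted over the list alone), among them KRT2 (-1.84), FLG (-1.25) and LCE1A (-1.78). The list passed with camera adjusted p = 4.01e-12 (adjusted p = 0.0619 with an estimated correlation). Of the 17 alarmins and stress keratins 4 fell (5 adjusted over the list alone), the keratins above and LCN2 (-1.14; -0.74, adjusted p = 0.281 without source 1 during replicate 48), an antimicrobial protein. As a list they had adjusted p = 0.00156 (adjusted p = 0.317 with an estimated correlation). Basal keratinocyte genes fell as a list, with KRT5 (-1.20) and KRT14 (-1.34) the 2 of 16 past the threshold (6 adjusted over the list alone; adjusted p = 9.71e-05 and 0.0356 with an estimated correlation). The interferon gamma and antigen presentation list fell, with 8 of 30 members down (11 adjusted over the list alone), among them GBP5, HLA-DRA and B2M (adjusted p = 4.68e-08 and 0.0356 with an estimated correlation). Immediate early genes, which respond to tissue handling as well as to signals, fell (3 of 18; 7 adjusted over the list alone; adjusted p = 3.4e-06 and 0.0356 with an estimated correlation). Ribosomal protein genes, a sign of RNA quality and depth, moved with these lists, with 10 of 39 down (31 adjusted over the list alone; adjusted p = 2.05e-33 and 0.05 with an estimated correlation).

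Among markers of other cell types in source 1, fibroblast genes fell (6 of 25, 7 adjusted over the list alone; adjusted p = 6.37e-06 and 0.158 with an estimated correlation). Macrophage genes fell as a list (1 rose and 3 fell of 33; 1 and 5 adjusted over the list alone; adjusted p = 0.0223 and 0.284 with an estimated correlation). Lists of B and plasma cells rose (3 up and 1 down of 17; 6 and 1 adjusted over the list alone; adjusted p = 0.017 and 0.115 with an estimated correlation), and lost the call with the signal-to-background covariate (0.0874), among genes above background (0.151) and under the strict filter (0.218), where no list was called higher. The blood list rose, with 0 of its 7 members past the edgeR threshold, 2 at an unadjusted p under 0.05 and 2 called by DESeq2 (2 adjusted over the list alone; camera adjusted p = 0.017 and 0.146 with an estimated correlation). Neutrophil genes rose with 2 of 14 up (2 adjusted over the list alone; adjusted p = 0.0299 and 0.115 with an estimated correlation). In all, 758 of 18,626 genes passed in source 1 (338 higher, 420 lower), and 36 of the 139 negative probes did (2 higher, 34 lower).

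The 13 during regions of source 1 fell into 2 sets, seen only after the values were examined: 7 stood apart from the other 6 in every region type (1 epidermis, 3 CD3+, 3 CD68+). Between the sets 1641 genes differed (842 higher and 799 lower in the 7, edgeR), ULBP1 lying at 793 to 1776 CPM in the 7 and 78.9 to 223 CPM in the 6. The sets were drawn from these same counts, so part of this number is built in. Ribosomal protein genes took 0.73 ± 0.39% of counts in the 7, 2.47 ± 1.08% in the other 6 and 2.31 ± 0.8% in the 11 before regions (mean ± SD). The 7 had a lower signal to background than the other 6, 1.15 to 1.379 against 1.544 to 2.328. The 11 before regions ran from 0.947 to 1.713, so by this ratio the 7 lay within their range and the other 6 reached above it. Without the 7 regions, KRT6A (-2.45 ± 0.36, adjusted p = 2.98e-08), KRT16 (-1.66), KRT17 (-1.85), PITX1 (-3.01), ANK1 (-2.26), KRT2 (-1.48) and GBP5 (-1.62) were still lower in source 1, and XRCC2 (1.32, adjusted p = 3.59e-09) and GFM2 (0.89, adjusted p = 0.0129) were still higher. ULBP1 (0.73, adjusted p = 0.204), FAM13B (0.83, adjusted p = 0.0943), ZNF714 (0.36, adjusted p = 0.754), LCN2 (-0.56, adjusted p = 0.471), KRT5 (-0.61, adjusted p = 0.221), KRT14 (-0.77, adjusted p = 0.0995), HLA-DRA (-0.10, adjusted p = 0.941), B2M (-0.25, adjusted p = 0.73), SOD2 and LYZ (-0.60, adjusted p = 0.329) no longer passed. Of the 758 genes, 186 passed in the same direction without the 7 and 663 without the other 6. The lists of alarmins (adjusted p = 0.427), basal keratinocytes (0.0562), ribosomal proteins (0.748), interferon gamma (0.086), blood (0.138) and neutrophils (0.447) lost their calls, and the fibroblast list turned direction (0.748).

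**Figure D2:**
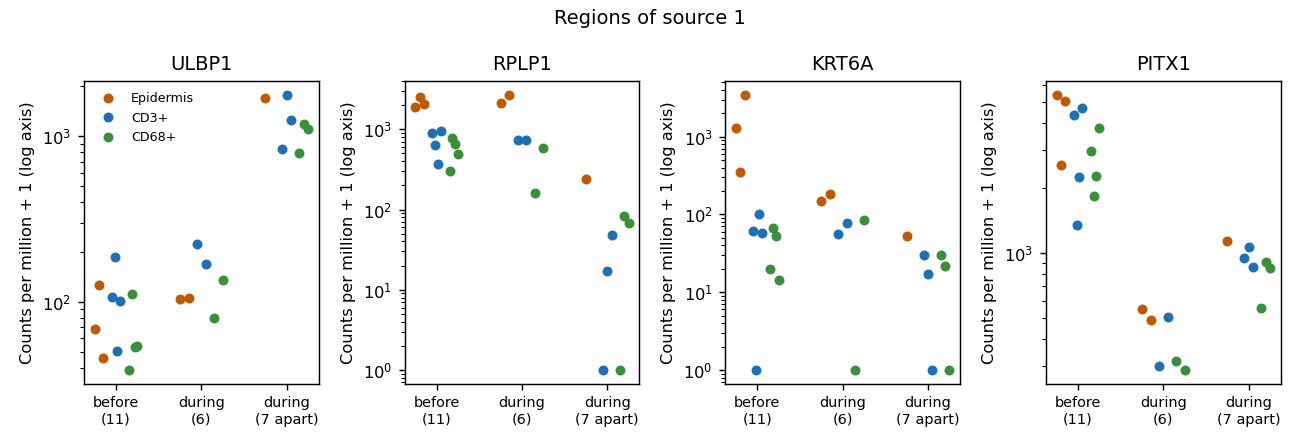
CPM plus 1 on a log axis in each region of source 1 for ULBP1, RPLP1, KRT6A and PITX1, with the 11 before regions, 6 during regions and the 7 during regions that stood apart; each point is 1 region, coloured by region type. ULBP1 separates the 7 regions from the rest, while PITX1 is lower in all 13 during regions than in all 11 before regions.

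The effect within source 2, by the sample labels, ran the other way for the epidermal stress genes. KRT6A rose (2.67 ± 0.27, adjusted p = 7.6e-17), with KRT16 (1.79 ± 0.27), KRT17 (1.69 ± 0.26) and SERPINB13 (1.57 ± 0.24), a keratinocyte protease inhibitor. The alarmins S100A8 (1.51 ± 0.26), S100A9 (1.19) and S100A7 (1.27), calcium-binding proteins of inflamed epidermis, also rose. In epidermis KRT6A went from 211 ± 45.2 to 3390 ± 1130 CPM and S100A8 from 6890 ± 5470 to 27500 ± 2970 CPM (SD, n = 3 each), with no overlap of the regions. PITX1 (1.57 ± 0.23), ANXA1 (1.30 ± 0.19), an anti-inflammatory phospholipid-binding protein, and IGFL4 (1.51) rose. Among the genes with the smallest p downward were KRT2 (-2.35 ± 0.34, adjusted p = 1.11e-07), ZNF671 (-2.23), NBPF11 (-1.15) and OR5L1 (-1.11), an olfactory receptor gene. Without source 2 before replicate 19 ZNF671 stood at -0.14 (adjusted p = 0.92).

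By gene list in source 2, 8 of 17 alarmins and stress keratins rose (11 adjusted over the list alone; adjusted p = 4.47e-19 and 0.0122 with an estimated correlation). So did basal keratinocyte genes (3 of 16; 5 adjusted over the list alone; adjusted p = 1.55e-05 and 0.0215 with an estimated correlation). The cornified envelope list rose as a whole with 10 of 51 up and 4 down (16 and 4 adjusted over the list alone; adjusted p = 3.01e-05 and 0.324 with an estimated correlation). KRT2 and FLG (-1.06) were among those that fell. Ribosomal protein genes rose beside them (8 of 39; 15 adjusted over the list alone; adjusted p = 3.81e-11 and 0.324 with an estimated correlation). Immediate early genes rose as well (6 of 18; 7 adjusted over the list alone; adjusted p = 1.55e-05 and 0.0793 with an estimated correlation). B and plasma cell genes (4 of 17, and 4 adjusted over the list alone; adjusted p = 0.014 and 0.149 with an estimated correlation) and interferon gamma genes (1 of 30, and 1 adjusted over the list alone; adjusted p = 0.0321 and 0.324 with an estimated correlation) rose as lists. T cell markers fell as a list (camera adjusted p = 0.014 and 0.324 with an estimated correlation), as did blood (camera adjusted p = 0.019 and 0.256 with an estimated correlation), with 0 of 34 and 0 of 7 members past the edgeR threshold and 0 of each adjusted over the list alone. At an unadjusted p under 0.05 edgeR gave 8 T cell and 2 blood genes, and DESeq2 called 0 of each. DESeq2 also called 0 of the 17 B and plasma cell genes and 0 of the 30 interferon gamma genes. In all, 504 genes passed by edgeR (423 higher, 81 lower). The split moved with scaling: 83.9% of the calls were higher under TMM, 51.8% under upper quartile scaling and 57.2% by DESeq2. With the 4 Immune regions left out 302 genes passed, and the lists of T cells (adjusted p = 0.0952) and blood (0.0736) lost their calls.

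**Figure D3:**
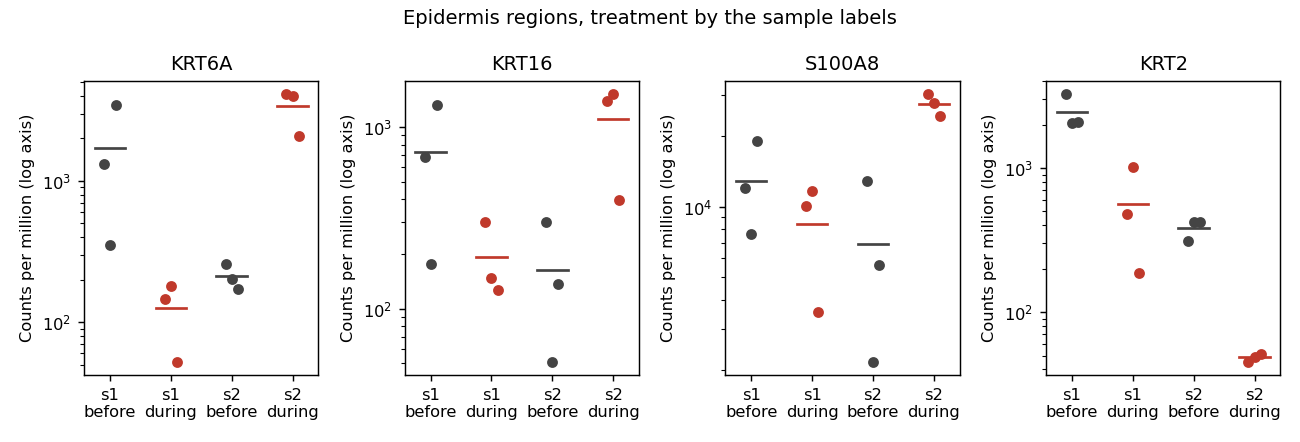
CPM on a log axis of KRT6A, KRT16, S100A8 and KRT2 in the epidermis regions of source 1 (s1) and source 2 (s2), treatment by the sample labels; each point is 1 region and the line is the mean of 3. KRT6A fell from 1700 to 126 CPM in source 1 and rose from 211 to 3390 CPM in source 2, while KRT2 fell in both.

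Whether the sources responded alike was tested by the difference of their effects (source 2 minus source 1). By the sample labels they moved apart in KRT6A (5.28 ± 0.48, adjusted p = 2.3e-20), PITX1 (3.85 ± 0.32, adjusted p = 1.4e-23), KRT16 (3.58 ± 0.40), ANK1 (3.24 ± 0.33) and AREG (2.95 ± 0.33), a ligand of the epidermal growth factor receptor. WNT8A (-2.08), NXF2 (-2.17), CDX2 (-2.30), ULBP1 (-2.29) and FAM13B (-2.12) rose more in source 1. Of 51 cornified envelope genes 23 differed (33 higher and 1 lower adjusted over the list alone; adjusted p = 2.94e-14 and 0.0358 with an estimated correlation). Of 17 alarmins 9 did (10 adjusted over the list alone; adjusted p = 3.76e-13 and 0.0218 with an estimated correlation). In all, 1062 genes differed (783 higher, 279 lower). So did 20 of the 139 negative probes (18 higher, 2 lower), or 14.39% against 5.72% of genes in that fit. Of the calls 73.7% were higher under TMM, 53.8% under upper quartile scaling and 36.7% by DESeq2. Across genes, which are not independent replicates, the effects of the sources correlated with Pearson r = -0.148, and 44.5% of genes had the same sign. With the headings of the count table r was 0.148 and 55.5% had the same sign. Counts simulated with no treatment effect, but with the fitted effect of signal to background, gave 0.279 to 0.306. A value of 0 need therefore not be the reference for either r. Genes that fell in source 1 and rose in source 2 numbered 39, against 9.54 if the calls were independent (Fisher's exact test, two-sided, p = 8.7e-14), and genes lower in both numbered 6, against 1.83 (p = 0.00994, exact). Genes higher in both numbered 6 (7.68 if independent, exact p = 0.711). These exact tests take genes as independent, which they are not, and both sets of calls share an estimate of the spread. Their p-values may therefore be too small. Without the 7 regions of source 1 that stood apart, 600 genes differed and ULBP1 did not (0.07).

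**Figure D4:**
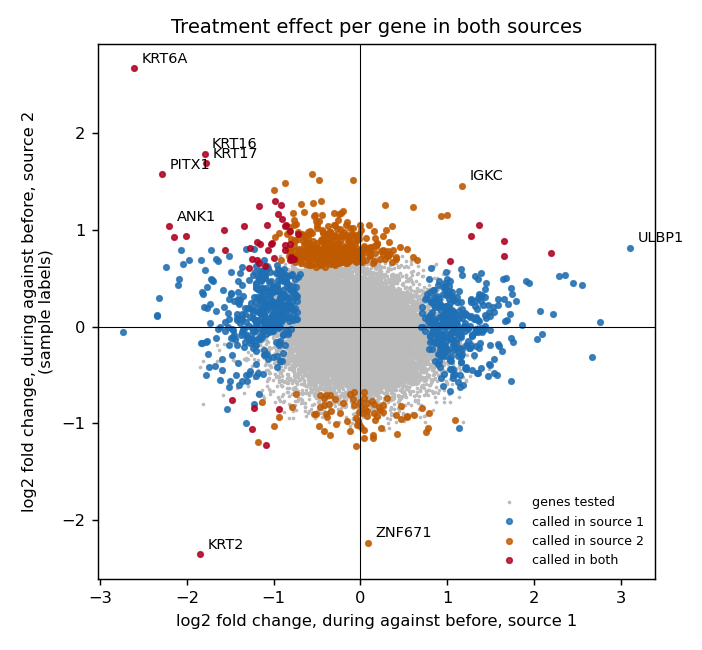
Log2 fold change during against before in source 1 (horizontal) and in source 2 by the sample labels (vertical) for 18,626 genes, with calls in either or both sources coloured. KRT6A, KRT16, KRT17 and PITX1 lie at negative values in source 1 and positive values in source 2, and KRT2 is negative in both.

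The mean of both sources asks which genes changed on average over the 2 people if the sample labels hold. A call there can rest on 1 source, so it does not show a change that both shared. Only 6 genes were called higher in both sources and 6 lower in both. Among the genes that fell were some of terminal keratinocyte differentiation: KRT2, a keratin of the upper epidermis (-2.10 ± 0.23, adjusted p = 2.81e-14), FLG (-1.16 ± 0.21), whose product bundles keratin in the stratum corneum, BLMH (-1.16 ± 0.20), which degrades it, TGM3 (-1.03 ± 0.19), which cross-links the cornified envelope, and LCE1A (-1.14). In epidermis KRT2 went from 2450 ± 679 to 560 ± 419 CPM in source 1 and from 386 ± 65 to 48.4 ± 3.08 CPM in source 2 (SD, n = 3 each), with no overlap in either. With source 2 turned to the table's headings the mean was 0.25 ± 0.22 for KRT2 (adjusted p = 0.598), -0.09 for FLG, 0.07 for BLMH and -0.19 for TGM3 (none called), and -0.64 for LCE1A (adjusted p = 0.0462). LYZ, the lysozyme of myeloid cells (-1.12 ± 0.17, adjusted p = 1.07e-07), S100A4 (-0.80), PRM1 (-1.40) and NETO1 (-1.04) also fell, though PRM1 stood at -0.19 (adjusted p = 0.834) without source 1 before replicate 29. Turned, LYZ was not called (-0.36, adjusted p = 0.217). ULBP1 rose (1.96 ± 0.19, adjusted p = 2.1e-18), with XRCC2 (1.41), GFM2 (1.45), FAM13B (1.49), BMERB1 (1.27), the zinc finger genes ZNF714, ZNF587 and ZNF845 (1.45, 1.19 and 1.19) and WNT8A (1.17), all with the larger part of the change in source 1. Turned, ULBP1 (1.15, adjusted p = 1.34e-06) and the others kept their calls except BMERB1 (0.38, adjusted p = 0.145). Without the 7 regions of source 1 the mean changes were smaller, at 0.76 for ULBP1, 0.93 for XRCC2, 0.71 for GFM2, 0.61 for FAM13B and 0.48 for WNT8A.

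By list, B and plasma cell markers rose in the mean (6 of 17; 6 up and 1 down adjusted over the list alone; adjusted p = 2.61e-04 and 0.0348 with an estimated correlation), the only one of the 6 called lists kept with an estimated correlation. DESeq2 called 2 of these 17, CD79B and IGKC. The IGHG genes of the list are close in sequence and may share signal. Cornified envelope genes fell (7 of 51; 12 adjusted over the list alone; adjusted p = 3.52e-04 and 0.528 with an estimated correlation). Macrophage genes fell as a list (1 up and 2 down of 33; 1 and 4 adjusted over the list alone; adjusted p = 7.56e-04 and 0.286 with an estimated correlation). Ribosomal protein genes (1 of 39; 5 adjusted over the list alone; adjusted p = 5.94e-08 and 0.603 with an estimated correlation) and interferon gamma genes (1 of 30, and 1 adjusted over the list alone; adjusted p = 0.0022 and 0.413 with an estimated correlation) fell as lists. So did fibroblast genes (camera adjusted p = 3.52e-04 and 0.528 with an estimated correlation), with 0 of 25 members past the edgeR threshold, 9 at an unadjusted p under 0.05, 2 called by DESeq2, and 1 up and 4 down adjusted over the list alone. Without the 7 regions of source 1 that stood apart, the ribosomal list rose (adjusted p = 4.86e-08) and the fibroblast (0.556) and interferon gamma (0.934) lists turned direction. Alarmins were then called upward (1.27e-07) and T cell markers downward (0.0331) in the mean. The cornified envelope list lost its call (0.309), while KRT2, FLG (-0.97), BLMH (-0.94) and TGM3 (-0.94) kept theirs.

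The drug's own target system was weakly detected. IL1A (0.19 ± 0.24, adjusted p = 0.842), IL1B (-0.17 ± 0.22, adjusted p = 0.844), IL1RN, which encodes the protein given as anakinra (0.29 ± 0.19, adjusted p = 0.604), and IL1R1, its receptor (0.24 ± 0.19, adjusted p = 0.681), did not pass in the mean. Their group means lay close to the negative probes, except IL1RN in epidermis, at 75.7 ± 23.2 to 167 ± 87 CPM (SD, n = 3 each). None of the 25 IL-1 family and inflammasome genes passed by edgeR in the mean, in source 1 or in source 2. At an unadjusted p under 0.05 there were 4, 5 and 3, DESeq2 called 0, 1 (IL36RN) and 0, and adjusted over the list alone 1, 0 and 0 passed. The list was not called (camera adjusted p = 0.828, 0.917 and 0.617). IL-17 and IL-23 axis genes gave 2 of 21 down in source 1, the antimicrobial genes DEFB4B (-1.45; -0.76, adjusted p = 0.216 without source 1 before replicate 51) and LCN2 (3 up and 2 down adjusted over the list alone; camera adjusted p = 0.491), and 1 down in source 2 (2 adjusted over the list alone; 0.362). NF-kB and IL-1 induced genes gave 2 of 28 down in source 1, CXCL2 (-1.37), a neutrophil chemokine, and SOD2 (-1.10; -0.35, adjusted p = 0.679 without the 7 regions), and 1 up and 1 down in source 2 (camera adjusted p = 0.266 and 0.523). In the mean 1 passed, CXCL1 (0.80, adjusted p = 0.0201), another neutrophil chemokine, which rose (camera adjusted p = 0.563 for the list, direction down). CXCL1 kept its call without the 7 regions (0.83, adjusted p = 0.0352) and lost it without 1 single region (highest adjusted p = 0.0833).

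**Figure D5:**
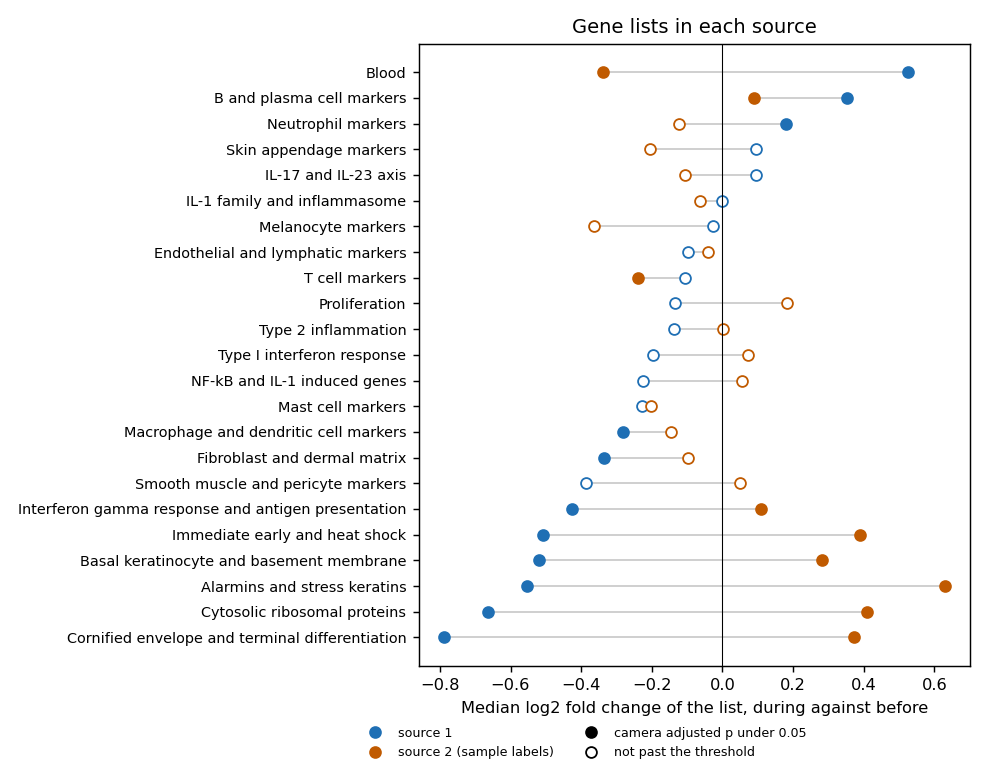
Median log2 fold change during against before of each of the 23 gene lists in source 1 and in source 2 (sample labels); filled points passed camera at an adjusted p under 0.05. The median of the cornified envelope list was -0.788 in source 1 and 0.372 in source 2, and that of the alarmins -0.554 and 0.631.

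For the mean, 266 genes passed in all (150 higher, 116 lower), and 89 of them passed in the same direction without the 7 source 1 regions that stood apart, where ZNF714 (adjusted p = 0.268) and BMERB1 (adjusted p = 0.0566) no longer did. Of the 139 negative probes 18 passed in the mean too (12.95%, against 1.46% of genes in that fit). Regions of 1 biopsy are not independent people, so these p-values measure the spread between regions and are too small. With the source and treatment set as a random block limma voom called 44 genes, a change of tool as well as of block, with a correlation of 0.01 within sets. There are 4 such sets and the model already holds source and treatment. That correlation is thus poorly estimated and does not show that regions of 1 biopsy are independent. In sums of counts per source and treatment, where each person is the replicate (n = 2), no gene passed by edgeR (399 at an unadjusted p under 0.05; DESeq2 also 0), the smallest adjusted p being 0.0909 for ZNF671 (log2 -1.54, and -0.08 without source 2 before replicate 19).

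Treatment effects within each region type ask where in the skin the change lay. In epidermis KRT2 (-2.54 ± 0.27, adjusted p = 8.67e-15), BLMH (-1.44), LCE1A (-1.33), TGM3 (-1.29) and C1orf68 (-1.28), a cornified envelope gene, fell. MUCL1, a secreted mucin-like gene of sweat glands (1.62 ± 0.27, adjusted p = 2.83e-05), OTUD1 (1.41) and IGFL4 (1.24) rose. With source 2 turned none of KRT2 (0.44), BLMH (0.32), TGM3 (-0.20), C1orf68 (-0.47) and MUCL1 (-0.47) was called in epidermis, LCE1A (-0.83) and OTUD1 (1.07) were, IGFL4 reversed (-1.24, adjusted p = 0.00112), and 336 genes passed (27 higher, 309 lower). Without source 1 during replicate 37 OTUD1 (0.30, adjusted p = 0.904) and IGFL4 (1.14, adjusted p = 0.142) lost their calls. In CD3+ regions IGKC, the immunoglobulin kappa constant chain (2.63 ± 0.42, adjusted p = 1.28e-05), and PTK6 (1.40) rose, and LYZ (-1.27 ± 0.29, adjusted p = 0.0184) and PRM1 (-2.55) were the 2 genes that fell. IGKC lost its call without source 1 during replicate 38 (1.73, adjusted p = 0.279), and LYZ without any 1 of 8 regions (adjusted p up to 0.135). Turned, neither was called (-0.19 and -0.04). In CD68+ regions IGHG3 (1.96 ± 0.38, adjusted p = 0.00392), IGHG2 (1.74) and IGHG4 (1.54), immunoglobulin heavy chain genes whose close sequences leave the member uncertain, rose. LYZ (-1.58 ± 0.28, adjusted p = 9.39e-04), PLTP (-1.56), a lipid transfer protein, GSN (-1.35), which severs actin, and CTSB (-1.15), a lysosomal protease, fell there. Each of these but LYZ lost its call without 1 or more single regions: IGHG3, IGHG2 and IGHG4 without source 1 during replicate 39 (adjusted p = 0.111, 0.165 and 0.175), PLTP without 1 region (0.0547), GSN without any 1 of 6 and CTSB without any 1 of 9. Turned, LYZ (-1.14, adjusted p = 0.0474) alone of these was called. By the sample labels, with each region left out in turn, GSN stayed at -1.52 to -1.22 and CTSB at -1.30 to -1.03. LYZ in CD68+ regions went from 576 ± 311 (n = 4) to 89.3 ± 75.4 CPM (n = 5) in source 1 and from 522 ± 211 to 363 ± 101 CPM (SD, n = 4 each) in source 2. Of the 5 source 1 regions 3 are among the 7 that stood apart, and without the 7 LYZ was still called in CD68+ regions (-1.12, adjusted p = 0.0347) but not in source 1 alone. Replicates 36 and 39 of source 1 during then remained, 36 being the shallowest of all 50 regions (11,953 gene counts). ULBP1 rose in all 3 region types (1.75 in epidermis, 2.00 in CD3+ and 1.91 in CD68+ regions). In epidermis it stood at 0.47 (adjusted p = 0.611) without source 1 during replicate 48, 1 of the 7, and in CD68+ regions it lost its call without source 2 during replicate 12 (1.69, adjusted p = 0.104). Without all 7 it was called in none of the 3 types (0.51, 0.95 and 0.69).

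Genes past the threshold numbered 46 in epidermis (25 higher, 21 lower), 18 in CD3+ (16 higher, 2 lower) and 29 in CD68+ regions (18 higher, 11 lower). Without the 7 source 1 regions these counts were 263, 7 and 10, and PRM1 in CD3+ regions stood at 0.34 without source 1 before replicate 29. The difference between the epidermal effect and that of CD3+ and CD68+ regions passed for no gene by edgeR (1379 at an unadjusted p under 0.05; DESeq2 also 0, with 1043). The smallest p-values were for CSTB, a protease inhibitor (1.54, adjusted p = 0.22), and IGKC (-2.20, adjusted p = 0.267), so a call in one region type alone does not show that the types differed.

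Region types were compared over both treatments to check their labels. Epidermis exceeded CD3+ and CD68+ regions in CALML5, a calcium-binding protein of differentiating keratinocytes (5.10 ± 0.18, adjusted p = 4.65e-93), KRTDAP (4.95), DMKN (4.98), FLG (5.02), KRT1 (5.23), S100A7 (5.16), S100A8 (5.15) and S100A9 (5.17). The check genes KRT5 (3.96) and KRT14 (3.79) were also higher there. Of the other check genes CD68 was lower in epidermis (-1.20), while CD3E was not called (-0.28). CD3+ and CD68+ regions held more of the dermal matrix genes COL3A1 (-2.82 ± 0.20) and COL6A2 (-2.46), of complement C3 (-2.91), of the chemokine CCL19 (-2.36) and of CD74 (-2.71), the invariant chain of antigen presentation. Of 51 cornified envelope genes 47 were higher in epidermis (47 adjusted over the list alone; camera adjusted p = 5.13e-129), and of 25 fibroblast genes 22 were lower (1 higher and 23 lower adjusted over the list alone; 1.06e-35). In all, 4387 genes differed (3696 higher, 691 lower). Of the calls 84.2% were higher under TMM and 62.7% by DESeq2. Regions were chosen by stain, so the keratin difference follows from the choice.

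Against CD3+ regions, 7 of 20 endothelial markers (9 adjusted over the list alone; camera adjusted p = 4.12e-18 and 2.79e-04 with an estimated correlation) and 8 of 25 fibroblast genes (14 adjusted over the list alone; 2.46e-24 and 0.00158) were higher in CD68+ regions. Among the genes higher there were PECAM1 (1.41 ± 0.24), VWF (1.39) and PLVAP (1.45) of endothelium, DCN (1.03) and COL1A1 (1.04) of matrix, and TPSAB1 (1.38 ± 0.23, adjusted p = 5.09e-06), the mast cell tryptase. CD3+ regions held more of the T cell genes TRAC (-2.93 ± 0.29 for CD68+ against CD3+), TRBC1 (-2.72), IL7R, LTB (-1.73) and IL32 (-2.90 ± 0.24, adjusted p = 1.46e-24). Of 34 T cell markers 11 were lower in CD68+ regions (22 adjusted over the list alone; camera adjusted p = 4.07e-36), beside 2 of 39 ribosomal protein genes (13 adjusted over the list alone; 7.07e-20 and 0.113 with an estimated correlation), and 2 of 33 macrophage markers were higher (7 higher and 1 lower adjusted over the list alone; 1.25e-09). CD3E (-1.65, adjusted p = 0.00294) passed and CD68 itself (0.56, adjusted p = 0.252) did not. In all, 132 genes differed (54 higher, 78 lower). Of the calls 40.9% were higher under TMM, 31.1% under upper quartile scaling and 77% by DESeq2. By the table's headings each CD3+ region shares its outline with 1 CD68+ region (17 outlines), which the model leaves out. With the outline as a block 204 genes differed (67 higher, 137 lower), 122 of the 132 among them, and CD68 again did not (0.54, adjusted p = 0.193). In that fit 9 ribosomal protein genes were lower (camera adjusted p = 9.58e-33 and 0.0148 with an estimated correlation) and 2 of 16 basal keratinocyte genes higher (2.05e-04 and 0.0148). These 2 were the check genes KRT5 (0.57, adjusted p = 0.00472) and KRT14 (0.76, adjusted p = 0.0243). Neither was called in the main model (adjusted p = 0.452 and 0.223).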

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

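The following tests were chosen only after the results were seen: the splits for CD68+ against CD3+ regions alone and within outlines, the correlation with the signal-to-background covariate and its simulation, the table headings, the shift of background, the 7 source 1 regions and the thinning. Splits of the regions at random within source and region type excluded chance, as far as spread between regions of the same biopsies goes, for most counts. The real split alone (1 of 100) reached the real count in the mean of both sources (266 genes, highest other 119), source 1 (758, highest other 268), source 2 (504, highest other 71), the difference between sources (1062, highest other 56), epidermis (46, highest other 35), CD3+ (18, highest other 6) and CD68+ regions (29, highest other 7). Chance was also excluded for the lists of source 1 (11, highest other 8) and source 2 (9, highest other 8) and for the size of the correlation (0.148, highest other 0.103). The same held for epidermis against the other types, 1 of 60 splits (4387 genes, highest other 299). Counts simulated with no treatment effect gave correlations of 0.279 to 0.306, so the size of 0.148 stands out against the splits alone. For CD68+ against CD3+ regions (132 genes) chance was not excluded by splits of all 3 region types, 5 of 60 reaching that count (highest other 655). It was when CD3+ and CD68+ labels alone were exchanged, 1 of 60 (highest other 6), and when they were exchanged within outlines with the outline as a block (204 genes), 1 of 40 (highest other 14). Chance was not excluded for the lists of the mean, where 16 of 100 splits gave 6 or more (highest other 8). For the difference between epidermis and the other types in their effects the splits give no test, since edgeR called 0 genes (1379 at an unadjusted p under 0.05, DESeq2 0), a count every split reaches (highest other 21). These splits permute regions, so they exclude neither an ordinary difference between 2 biopsies or sections of a person nor one between people. The treatment splits also move CD3+ and CD68+ regions of 1 outline separately, and the treatment models hold no outline. Spread shared within an outline (mean correlation 0.204) is thus not covered.

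Treatment effects differed between the sources by a test of the difference itself in 1062 genes. Keratins and regulators moved up in source 2 relative to source 1: KRT6A (5.28), PITX1 (3.85), KRT16 (3.58), ANK1 (3.24) and AREG (2.95), while WNT8A (-2.08), NXF2 (-2.17), CDX2 (-2.30), ULBP1 (-2.29) and FAM13B (-2.12) moved the other way. Of these, 39 genes passed downward in source 1 and upward in source 2. With the signal-to-background ratio as a covariate the correlation across genes turned to 0.233. Counts simulated with no treatment effect gave 0.27 to 0.298 in that model and 0.279 to 0.306 without the covariate. The observed 0.233 lay a little below its range and -0.148 far below. The simulated counts held the fitted effect of the ratio, so they do not show the value without a background difference, and the turn decides nothing. Whether a difference in background lies behind the negative correlation stays open. All 39 opposite genes still differed with that covariate (KRT6A -3.84 in source 1 and 2.34 in source 2), which argues against background, as that ratio measures it, as the whole cause for them. They were chosen for opposite calls in these same data. The covariate model also called more genes for the difference than the main model, which limits what their survival can show. A reversal of the treatment record of source 2 cannot be told apart from opposite effects: headings oppose labels for 26 of its 26 regions. For source 1 the region numbers of the series text (13 before, 11 during) are the reverse of its labels, so a reversal there is not excluded either. No further record was used here. A different response of the 2 people stays open as well, untested.

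Of the 758 genes called in source 1, 156 passed an unadjusted p under 0.05 in the same direction in all 3 region types (98 up, 58 down). In source 2 this held for 14 of the 504 called genes. The calls rest on the same regions, so part of this agreement is built in. Low depth is argued against, since 153 of the 156 were still called without the regions under 50% of the median depth. Without the 7 during regions that stood apart 60 were called, against 154 without the other 6, so those 7 regions may carry most of the pattern. A shift of background over whole sections also stays open: 25.9% of the negative probes were called in source 1 (4.16% of genes), and only 8 of the 156 genes moved beyond the range of the negative probes (-2.46 to 2.09). Of the 36 called probes 34 were lower while 98 of the genes rose, and these genes had a median of 130 CPM against 38.1 for the probes. Values are scaled to a common total, so a lower background can go with a rise of genes above it. The opposite directions therefore decide nothing. No biological explanation was tested, and 79 of the 156 had the same sign in source 2.

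Among the 13 during regions of source 1 the first component, with 46.6% of the variance, left a gap of 0.316 between 7 regions and 6, and 1641 genes differed between them. Sides of the other 3 sets of regions, drawn in the same way, differed in 18 to 34 genes. Each split was drawn from the counts that were then tested, so part of every such number is built in. After thinning all 13 regions to 11,901 counts 58 genes still differed, more than between the sides of any other set at full depth. Depth alone is thus argued against, though only as far as sets drawn from these same counts at full depth can show. A background shift may be part of it, as 10.79% of the negative probes were called between the sets (8.81% of genes). The 7 were replicates 40 to 45 and 48 and the other 6 were replicates 34 to 39, so the sets follow the numbering of the regions. CD3+ and CD68+ regions of 1 outline are not independent, so the region types do not repeat the split separately. The labels name no section or position, and a different place in the tissue was not tested.

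Of the 139 negative probes, 36 passed in source 1 (2 higher, 34 lower), 2 in source 2 and 18 in the mean. For the difference between the sources 20 passed (18 higher, 2 lower). As shares, 12.95% of the probes passed in the mean (1.46% of genes in that fit) and 14.39% for the difference (5.72% of genes). In source 2 the share was 1.44% (2.7% of genes). The technical control held 5 counts in all, from 77 aligned reads. Single regions lay far from the others of their group for IL1A (15 CPM, source 1 before, CD3+, replicate 29) and KRT2 (101 CPM, source 2 before, CD68+, replicate 18). The same held for IGKC in 2 groups (56.6 CPM in source 1 before, CD68+, replicate 30, and 490 CPM in source 1 during, CD3+, replicate 38). Of 88 groups tested 4 held such a region, against 4.4 by chance.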

How the results depend on the processing

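The headings of the count table, genes above background and both sets of source 1 regions were alternatives chosen after the data were seen. Counts under upper quartile scaling and without a filter stayed within 1.5 times those reported. Single regions left out and the headings aside, of 4542 single-gene results 3894 kept direction and side of the threshold, 386 lost and 217 gained a call, 40 uncalled ones changed otherwise and 5 reversed; of 743 list results these were 620, 59, 10, 48 and 6. Where counts changed, the cause was not tested, except that fewer genes or regions were tested under the filters and the regions left out. All regions of both sources share an estimate of the spread, so regions of source 1 also bear on the calls of source 2. Without source 1 during replicate 48, 723 genes passed in source 2, against 504 with all regions. The counts of source 2 without either set of source 1 regions carry the same limit. DESeq2 gave 39 genes in CD3+ and 51 in CD68+ regions. The strict filter (1067 genes) gave 303 in source 1, 134 in source 2, 352 for the difference between sources, 11 in epidermis, 35 in CD3+ regions, 1 for the difference between region types' effects, 881 for epidermis against the others, 1, 2 and 1 lists (mean, source 1, source 2) and 13 of the 20 named genes. Limma voom with a random block gave 44 in the mean, 2 in epidermis, 0 in CD3+ (edgeR 18; DESeq2 39) and 1 in CD68+ regions, and could not give effects within a source. Without region type in the model 83 passed in the mean, 348 in source 1, 5 in source 2 and 209 for their difference. The signal-to-background covariate gave 1052 in the mean, 1977 in source 1, 1742 for the difference, 646 in epidermis, 284 in CD3+ and 158 in CD68+ regions, 9 for the difference between region types' effects, 2319 and 214 for the region comparisons, 7 lists in source 1, and reversed the correlation to 0.233. Without 9 shallow regions 1 gene passed in the sums, 5 in CD3+, 17 in CD68+ regions and 82 for CD68+ against CD3+. Without Immune regions 302 passed in source 2 and 1 in the sums.

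With source 2 turned to the headings, 1062 genes passed in the mean, 504 in source 2 reversed, and 266, 5, 336 and 8 passed for the difference, the sums, epidermis and CD3+ regions. There were 5 for the difference between region types' effects, a correlation reversed to 0.148, 9 lists of source 2 reversed, and 13 named genes. The table with its headings gave 1089 in the mean, 829 reversed in source 2, 343 for the difference, 135 in the sums, 341 in epidermis, 4 in CD3+ and 15 in CD68+ regions. It gave 1 for the difference between region types' effects, a correlation reversed to 0.176, 7 lists of source 2 reversed and 11 named genes. Genes above background (3077) gave 296 in source 2, 21 in epidermis, 1983 for epidermis against the others, a correlation of -0.227 and 5 and 4 lists in source 1 and source 2. Without the 7 source 1 regions that stood apart 284 passed in source 1, 1198 in source 2, 600 for the difference, 1 in the sums, 263 in epidermis, 7 in CD3+ and 10 in CD68+ regions, 9 for the difference between region types' effects, and 4 lists in source 1. Without the other 6 there were 1713 in the mean, 2780 in source 1, 1050 in source 2, 3032 for the difference, 492 in epidermis, 276 in CD3+, 184 in CD68+ regions and 1 for the difference between region types' effects, with 1 epidermis region left in that set and assumed to vary like the others.

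With the outline that a CD3+ and a CD68+ region share as a block, also chosen after the data were seen, 204 genes differed between these types. The interferon gamma list of source 2 reversed under the strict filter (adjusted p = 0.727) and among genes above background (0.968). Without the 7 regions lists reversed for ribosomal proteins (4.86e-08), fibroblasts (0.556) and interferon gamma (0.934) in the mean and fibroblasts in source 1 (0.748). So did ULBP1 in the difference (0.07), and RPLP1 (0.03), GATA2 (-0.85) and IFITM3 (-0.33) in source 1. OTUD1 in epidermis reversed without the other 6 (-0.48), and PRM1 in CD3+ regions without source 1 before replicate 29 (0.34).

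Leaving out each region in turn gave 176 to 368 genes in the mean, 431 to 958 in source 1, 200 to 723 in source 2, 772 to 1345 for their difference, 0 to 1 in the sums, 19 to 75 in epidermis, 13 to 31 in CD3+, 12 to 67 in CD68+ regions, 0 to 19 for the difference between region types' effects, 3715 to 4846 and 106 to 162 for the region comparisons, a correlation of -0.153 to -0.127, 6 to 8, 10 to 12 and 7 to 10 lists, and 19 to 20 named genes. Counts moved over 1.5 times without source 1 during replicate 48 (mean 176, source 1 431, epidermis 75, region types' effects 19), replicate 37 (epidermis 72), 38 (CD3+ 31), 39 (CD68+ 67), 43 (CD68+ 12) and 45 (CD68+ 13). They did without source 1 before replicate 28 (epidermis 19), 51 (epidermis 25), 33 (CD68+ 19) and 50 (CD68+ 18). In source 2 they did without during replicate 2 (source 2 292, epidermis 24), 5 (314, 24), 23 (317) and 12 (CD68+ 17), and before replicate 13 (306, 26), 16 (274, 27) and 19 (200, 19). The sums gave 1 gene without source 2 before replicate 24, source 1 before replicates 28 and 51 or source 1 during replicates 35, 42 and 48. Scaling moved the median change of all genes in source 2 by -0.11 (upper quartile) and -0.17 (DESeq2), in the difference by -0.15 and -0.28, in the region types' effects by -0.17 (upper quartile), and by DESeq2 in the region comparisons by -0.20 and 0.21. Calls in the mean were 56.4% higher under TMM and 45.2% under upper quartile scaling, in source 1 44.6% and 60.1% by DESeq2, in epidermis 54.3% and 29.8% under upper quartile scaling, in CD68+ regions 62.1%, 82.1% under upper quartile scaling and 52.9% by DESeq2, and in CD3+ regions 88.9% and 69.2% by DESeq2.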

Other observations

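Read within 1 source and region type, by the sample labels, macrophage and dendritic cell markers fell in the CD68+ regions of source 1: 5 of 33 members (14 adjusted over the list alone), with a median log2 change of -1.204 (camera adjusted p = 7.49e-12 and 1.12e-04 with an estimated correlation). Fibroblast genes fell there beside them, 5 of 25 (10 adjusted over the list alone; adjusted p = 2.3e-12 and 0.0459 with an estimated correlation), as did ribosomal protein genes as a list (median -0.813, adjusted p = 2.71e-22 and 0.141 with an estimated correlation). Of the 5 during regions there 3 are among the 7 that stood apart. Without those 7, a test added after the values were seen, macrophage markers still fell (3 of 33, median -1.15, adjusted p = 5.39e-12 and 9.5e-05 with an estimated correlation), while the fibroblast (0.867) and ribosomal lists (0.0862) were not called. That left replicates 36 and 39 during treatment. Replicate 36 had the fewest gene counts of all 50 regions (11,953, with 59.41% of genes at 0). In the CD68+ regions of source 2 B and plasma cell genes rose, 4 of 17 (4 adjusted over the list alone; adjusted p = 2e-06 and 0.00255 with an estimated correlation). IGKC, a member of that list, ran there from 55.4 to 2453 CPM during and from 71.5 to 636 CPM before treatment. In source 2 epidermis 10 of 17 alarmins and stress keratins rose (14 adjusted over the list alone; adjusted p = 2.29e-23 and 0.00131 with an estimated correlation), and in source 1 epidermis 17 of 51 cornified envelope genes fell (25 adjusted over the list alone; adjusted p = 7.74e-31 and 9.24e-04 with an estimated correlation), as 15 did without the 7 (8.02e-19 and 0.00488). Melanocyte markers fell in source 2 epidermis, 2 of 8 (2 adjusted over the list alone; adjusted p = 0.00109 and 0.0166 with an estimated correlation). Within a region type the treatment effect differed between the sources in 336 genes in epidermis, 8 in CD3+ and 38 in CD68+ regions.

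Epidermis held more IL-1 family genes than CD3+ and CD68+ regions, 9 of 25 (11 adjusted over the list alone; camera adjusted p = 0.0444 and 0.0677 with an estimated correlation), and more proliferation genes, 15 of 28 (16 adjusted over the list alone; adjusted p = 0.00804 and 0.102 with an estimated correlation). Of the IL-17 axis genes 7 of 21 were higher there (7 adjusted over the list alone; adjusted p = 0.0807). Lists not called for treatment in source 1, in source 2 or in the mean had camera adjusted p of 0.266, 0.0656 and 0.869 (proliferation), 0.445, 0.119 and 0.858 (type I interferon), 0.992, 0.201 and 0.526 (type 2 inflammation), 0.491, 0.362 and 0.289 (mast cells), 0.832, 0.195 and 0.524 (melanocytes), 0.638, 0.784 and 0.563 (endothelium), 0.102, 0.362 and 0.499 (smooth muscle) and 0.266, 0.636 and 0.526 (skin appendages). T cell markers had 0.688 in source 1 and 0.0961 in the mean, neutrophils 0.768 in source 2 and 0.0961 in the mean, and alarmins 0.0644, basal keratinocytes 0.526, blood 0.526, immediate early genes 0.187, IL-17 axis 0.963 and NF-kB genes 0.563 in the mean. Median, mean and test differed in sign for some uncalled lists: in source 1 the IL-1 family had a median of 0.000, a mean of -0.092 and a camera direction up, the IL-17 axis 0.094, -0.032 and up, and type 2 inflammation -0.136, -0.048 and up. Fibroblast genes in source 2 had -0.097, -0.044 and up, and neutrophil genes in the mean -0.013, 0.056 and up.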
